A study of Danio rerio with 15 samples.

How the data were processed

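Total RNA of whole zebrafish larvae was extracted with the RNeasy Mini kit, and Cy3-labelled cRNA made from 0.2 µg of it was hybridised to one-colour Agilent arrays, per the labels, with 15 arrays in 5 groups of 3. Per the file headers the scanner values are intensity, background-subtracted and detrended by Feature Extraction 11.0.1.1 on an array design annotated on danRer7 (Zv9), whereas the submitters' notes name version 10.10. The value table that the authors deposited holds log2 values, scaled to each array's 75th percentile and centred per probe: its differences between arrays lay within 0.1 of those of the scanner values for 99.5% to 100% of probes. Slide and position on the slide came from the headers.

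Each array held 45220 spots, of which 1417 control spots were left out. Spots of one probe were averaged on the log2 scale, giving 43603 probes. A probe took the symbol of its transcript in a RefSeq gene table (GRCz12tu), which named 25854 probes of 13293 genes. The 17749 probes without a name stayed as their own features. For the 7866 genes with several probes the probe with the highest mean log2 intensity over the 15 arrays was used. Probes had to be well above background on all arrays of at least 1 group, which 34556 did, leaving 23790 features, called genes in the text, 12083 of them with a symbol. No chromosomal positions are given, since the reference table and the array design use different builds. The stress gene gstp1 was read as gstp1.1, the name in the list fixed beforehand; the gene table gives gstp1 as a synonym of gstp1.2, whose values are printed where it passed.

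The log2 intensity minus each array's 75th percentile was fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend, prior degrees of freedom 4.13), with 5 group means over all 15 arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 9 comparisons. Tested on simulated data with 200 changed genes per run for 50 nm against control, the fit recovered 38.2% at 1.5-fold, 74% at 2-fold and 94.2% at 4-fold, with 5.6 false calls per run over 5 runs. The simulated noise was independent between genes and arrays and held no slide effect, so these figures do not cover false calls from slides. A gene near background in one group is given as a bound. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

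The comparisons, tests, gene lists, named genes and alternatives were chosen before the data were examined, except where the text says otherwise. Named genes are, in the 4 comparisons with control and that of the sizes, the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap between groups, with a symbol and well above background in both groups; where none passed, the 5 smallest p. To these come up to 4 members, by smallest p, of each list that passed, the 10 genes with the largest mean change called in one direction in all 3 silver groups, and 12 stress genes whatever their result (mt2, hmox1a, hsp70l, gstp1, sod1, sod2, cat, gpx1a, cyp1a, atf3, il1b, and 1 whose name is withheld from this text). In the other 4 comparisons only list members are named. The clock genes named beyond this were chosen after their values were seen.

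The 23 lists, with 1101 members tested, cover metal binding and transport, antioxidant and glutathione, heat shock and chaperone, unfolded protein response, inflammation, apoptosis, cell cycle, xenobiotic metabolism, sterol biosynthesis, ionocyte, oxidative phosphorylation, proteasome, circadian clock, pancreatic enzyme, hepatocyte, enterocyte, skeletal muscle, neural, photoreceptor, lens crystallin, epidermis, erythrocyte and heme, and leukocyte genes. They were tested with camera at a preset correlation of 0.01 (main), with an estimated correlation, and with fry, adjusted over the lists of a comparison; where fold changes and spreads had to be complete, 412 values were filled. Members were counted over all genes and adjusted over the list alone.

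Alternatives were normexp background correction (offset 50, on median intensity, as mean intensity is not among the columns), quantile normalization, no dim filter, a stricter filter (all 15 arrays), the mean of a gene's probes, only the 2 groups compared, slide as a block, the replicate number as a block, array weights, the deposited value table, at least a 2-fold change, each array left out in turn, and separate controls for overlaps. Slide was a fixed block for the 6 comparisons without AgNO3 and a random block (correlation 0.336) for those with it; the random block for the other 6 was chosen after seeing the data. Left out were control spots and single spots that the scanner software marked as outliers.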

Results

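Gene expression was measured in whole zebrafish larvae on one-colour Agilent arrays, where the Cy3 fluorescence of each probe is read as an intensity. The larvae were 72 hours past fertilisation when exposure began. They received silver nanoparticles of 50 nm or 150 nm at 1 mg/L, the particle coating polyvinylpyrrolidone (PVP) at 0.1 mg/L, silver nitrate (AgNO3, the labels' positive control) at 20 µg/L, or nothing (control). Each of the 5 groups had 3 arrays, so the number of arrays limits the precision of every value. The labels give an exposure of 96 hours, while their description field gives 36 hours, and the values do not settle which holds. By its title the series asks how particle size affects global gene expression. Nothing in the labels says that replicates are separate cultures or animals, so the p-values measure only the spread between these samples.

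The 75th percentile of intensity ran from 833.7 (control replicate 3) to 1369.6 (50 nm replicate 3), and no spot was saturated on the 15 arrays. Probes well above background made up 78.9% to 83.9% of probes in control arrays and 64.1% to 74.2% in 50 nm arrays. Correlations across genes between replicates, where genes are not independent, were 0.994 to 0.997 in controls and 0.976 to 0.985 in the 50 nm group. The first principal component (33.9% of the variance) set the AgNO3 arrays (60.5 to 66.8) apart from the rest (−43.4 to −6). The second (16.1%) held 50 nm replicate 3 at its lower end (−58.7). The arrays lay on 4 slides: slide 1 held the controls and PVP replicate 1, slide 2 held PVP replicates 2 and 3 and 50 nm replicates 1 and 2, slide 3 held 50 nm replicate 3 and the 150 nm arrays, and slide 4 held the AgNO3 arrays alone. AgNO3 and slide 4 therefore cannot be told apart.

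In what follows a value after a gene symbol is its log2 fold change ± SE from limma with 3 arrays per group, and "rose", "fell" and "changed" mark an adjusted p under 0.05 over 23790 genes. Of these, 12083 had a gene symbol, and the others were probes without one. With slide as a fixed block, PVP against control rests on PVP replicate 1 alone against the controls, 50 nm against PVP on the 2 arrays of each on slide 2, and the sizes on 50 nm replicate 3 alone against the 150 nm arrays. The other 3 comparisons without AgNO3 add these up, so they too rest on single arrays. Gene lists were fixed beforehand, and their members all have a symbol. They were set against all other genes, many of them without one. Where those lean one way a list can pass the other way, and this was not tested. The test used was camera at a preset correlation of 0.01. The test fry was run beside it: its directional p asks whether the genes of a set move on balance one way and its mixed p whether they change in either direction, and neither compares the set with other genes or sets.

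Larvae exposed to 50 nm particles, compared with controls, showed higher expression of leukocyte and inflammation genes as sets at the preset correlation, but not with an estimated one (adjusted p = 0.337 for both). The inflammation mean was 0.91 on 50 nm replicate 3, 0.17 and 0.10 on the other 2 arrays, and −0.20 to 0.10 in controls. Among the largest rises were rgs2 (2.64 ± 0.27), a regulator of G-protein signalling, odc1 (2.36 ± 0.35), which encodes the rate-limiting enzyme of polyamine synthesis, the somatostatin gene sst2 (2.48 ± 0.43), and the chemokine gene ccl20b (1.99 ± 0.36). Higher too were ifi44c1 (2.99 ± 0.65), of an interferon-induced family, the gelatinase gene mmp9 (2.32 ± 0.56), rnasel2 (1.96 ± 0.41), the potassium channel gene kcnj1a.3 (2.26 ± 0.45), the BMP antagonist gene grem1a (2.01 ± 0.35) and wdr76 (1.99 ± 0.20). On the PVP arrays of slide 2 grem1a was as high (0.12 and 0.50) as on the 50 nm arrays (0.06 to 0.88). The largest falls were in six7 (−1.62 ± 0.11), a transcription factor gene for cone opsins, pth2 (−1.29 ± 0.30), tspan34a (−1.22 ± 0.21), the cone opsin kinase gene grk7b (−1.20 ± 0.17), cpo (−1.19 ± 0.21), foxq1b (−1.18 ± 0.14), the nucleoside transporter gene slc28a1 (−1.18 ± 0.17), the lipase gene cel.1 (−1.15 ± 0.29), gig2g (−1.14 ± 0.27) and lrit1b (−1.11 ± 0.16). Near background in one group, rargb was at least 8.69-fold higher and cdc37l1 at least 6.16-fold lower. Such bounds, here and below, are differences of group means without an SE.

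Of 43 measured leukocyte genes, 12 rose and none fell, among them lyz (0.43 ± 0.10), which encodes lysozyme, arpc1b (0.60 ± 0.12), b2m (0.97 ± 0.24) and cd74b (0.71 ± 0.18); adjusted over the list alone 20 rose. Of 32 inflammation genes 7 rose, including the cyclooxygenase genes ptgs2a (1.08 ± 0.17) and ptgs2b (1.11 ± 0.20), with 7 higher and 1 lower adjusted over the list alone. Of 26 sterol biosynthesis genes 8 rose, including hmgcra (0.82 ± 0.20), msmo1 (0.72 ± 0.13) and hmgcs1 (0.78 ± 0.20), with 9 higher and 1 lower adjusted over the list alone. Sterol means per array were 0.51, 0.04 and 0.33 with 50 nm and −0.13 to 0.08 in controls, so 50 nm replicate 2 lay within the control range. Cell cycle genes had a median of 0.29 and 6 of 57 rose, smc4 (0.48 ± 0.13) and birc5a (0.66 ± 0.19) among them, but adjusted over the list alone 0 did. Cell cycle means per array were 0.57, 0.29 and 0.22 with 50 nm and −0.11, 0.29 and 0.05 in controls, so the groups overlapped. As sets, these lists lay above the other genes (adjusted p = 1.98e-08 for leukocyte and for cell cycle, 7.85e-07 for inflammation, 2.12e-05 for sterol biosynthesis). None passed with an estimated correlation (adjusted p = 0.337, or 0.397 for cell cycle), and the fixed slide block ended the sterol call (adjusted p = 0.0702).

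Ion transport and liver genes moved both ways, with 10 of 51 ionocyte genes higher and 4 lower (slc12a10.3 at 1.37 ± 0.20, kcnj1a.4 at 1.66 ± 0.32, the ammonia transporter gene rhcga at −0.67 ± 0.12) and 10 of 54 hepatocyte genes higher and 3 lower (fga, a fibrinogen gene, at 0.73 ± 0.13, apoa2 at 0.46 ± 0.09). Adjusted over the list alone the counts were 15 and 5 for ionocyte and 11 and 3 for hepatocyte genes. Ionocyte means per array were 0.52, 0.04 and 0.22 with 50 nm and −0.18 to 0.14 in controls, so 50 nm replicate 2 lay within the control range. Heme genes included slc25a38a (1.44 ± 0.12), a mitochondrial glycine transporter gene, and tspo (1.00 ± 0.16), with 5 of 38 higher and 2 lower. Antioxidant genes rose in 8 of 39 cases, including hmox1a (0.67 ± 0.14), gstp1.2 (0.83 ± 0.16) and cat (0.41 ± 0.13), and 2 fell, gpx1a (−0.40 ± 0.07) among them. The stress-induced factor gene atf3 rose (1.23 ± 0.17), and with dnajb11 (0.64 ± 0.18) it made 2 of 30 unfolded protein response genes. Set tests gave adjusted p = 0.000178 (ionocyte), 0.000145 (hepatocyte), 0.00648 (heme), 0.00122 (antioxidant) and 0.00195 (unfolded protein response), and 0.337 to 0.416 with an estimated correlation. With adjustment within the list 5 heme genes were higher and 3 lower, 11 and 3 antioxidant genes, and 1 and 0 unfolded protein response genes. The apoptosis list (adjusted p = 0.0108, 3 of 35 higher and 3 lower, plk3 at 0.58 ± 0.07, aifm1 at −0.55 ± 0.11) and the epidermis list (adjusted p = 0.0317, 7 of 55 higher and 3 lower, the tight junction gene cldnb at 0.90 ± 0.13) also lay higher, with the same counts adjusted over the list alone, and did not with an estimated correlation (adjusted p = 0.337 and 0.363) or with slide as a fixed block (adjusted p = 0.144 and 0.115).

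Muscle and neural genes lay lower as sets with 50 nm particles at the preset correlation, but not with an estimated one (adjusted p = 0.416 and 0.511). The neural call also ended with normexp background correction (adjusted p = 0.0584) and with slide as a fixed block (adjusted p = 0.888). Of 84 skeletal muscle genes 22 fell and 1 rose (myoz1a at −0.61 ± 0.10, actc1a at −0.67 ± 0.11, or 0.02 as the mean of its probes; adjusted over the list alone 30 and 1), and nebl was at least 2.59-fold lower. Of 68 neural genes 12 fell, such as the synaptotagmin gene syt5b (−0.46 ± 0.08), the glycine receptor gene glra4a (−0.62 ± 0.11) and elavl3 (−0.74 ± 0.16), and 13 adjusted over the list alone. Neural means per array were −0.14, −0.04 and −0.23 with 50 nm and −0.04 to 0.09 in controls. Of 88 oxidative phosphorylation genes 14 fell and 1 rose by both counts, ndufaf5 (−0.42 ± 0.07) and cox5aa (−0.35 ± 0.09) among them. Pancreatic enzyme genes had a median of −0.47, with 3 of 26 lower (cela1.3 at −1.31 ± 0.40) and 8 adjusted over the list alone. Their means per array were 0, 0.49 and −0.63 with 50 nm and 0.69, 0.40 and 0.39 in controls, so 50 nm replicate 2 lay within the control range. Lens genes had a median of −0.24 with 4 of 60 lower and 1 higher, crybb2 (−1.14 ± 0.34) and crybb3 (1.52 ± 0.47) among them, but 0 adjusted over the list alone. Lens means per array were −0.03, 0.20 and −0.43 with 50 nm and 0.25, −0.17 and 0.23 in controls, so only 50 nm replicate 3 lay below every control. The sets gave adjusted p = 2.63e-05 (muscle), 0.00997 (neural), 0.0039 (oxidative phosphorylation), 0.00255 (pancreas) and 0.0352 (lens), against 0.527, 0.568 and 0.73 for the last 3 with an estimated correlation. Quantile normalization ended the oxidative phosphorylation and lens calls (adjusted p = 0.141 and 0.524), and normexp the lens call (adjusted p = 0.0584). In fry 5 lists passed, inflammation, leukocyte, muscle, neural and oxidative phosphorylation, each with adjusted p = 0.0487.

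The other 7 lists did not pass, although the proteasome and enterocyte lists lay lower with slide as a fixed block (medians −0.35 and −0.31, adjusted p = 0.00018 and 0.000444). Their medians ran from −0.18 (enterocyte) to −0.01 (metal binding), and for metal binding, heat shock, xenobiotic metabolism and circadian clock genes the median was negative while the test pointed higher. Adjusted p was 0.114 for the metallothionein gene mt2 (0.53 ± 0.22), 0.127 for the heat shock gene hsp70l (1.04 ± 0.45) and 0.247 for il1b (1.36 ± 0.79), which in each silver group was well above background on 1 of 3 arrays. The rise in cat held without 50 nm replicate 3 and ended when any other array of the 2 groups was left out, while hsp70l passed only without 50 nm replicate 2. No change was called in sod1 (0.01 ± 0.09), sod2 (−0.07 ± 0.08), gstp1.1 (−0.12 ± 0.31) or cyp1a (−0.16 ± 0.18).

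In limma 3496 genes changed, 1112 higher and 2384 lower (68.2% lower, or 46.2% without the dim filter), and 466 changed at least 2-fold. The groups did not overlap at 7673 genes (32.6%, where chance gives 10%). The count was 770 and 884 without control replicates 1 and 3, 1572 without 50 nm replicate 1, and 296 with only these 2 groups. With slide as a random block 414 genes changed, all of them among the 3496, and with slide as a fixed block 11 did, 8 of them shared. Of the 20 named genes with the largest changes the random block kept 12, dropping for instance mmp9 (adjusted p = 0.102) and ifi44c1 (adjusted p = 0.0777), while the fixed block kept wdr76 and six7.

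**Figure D1:**
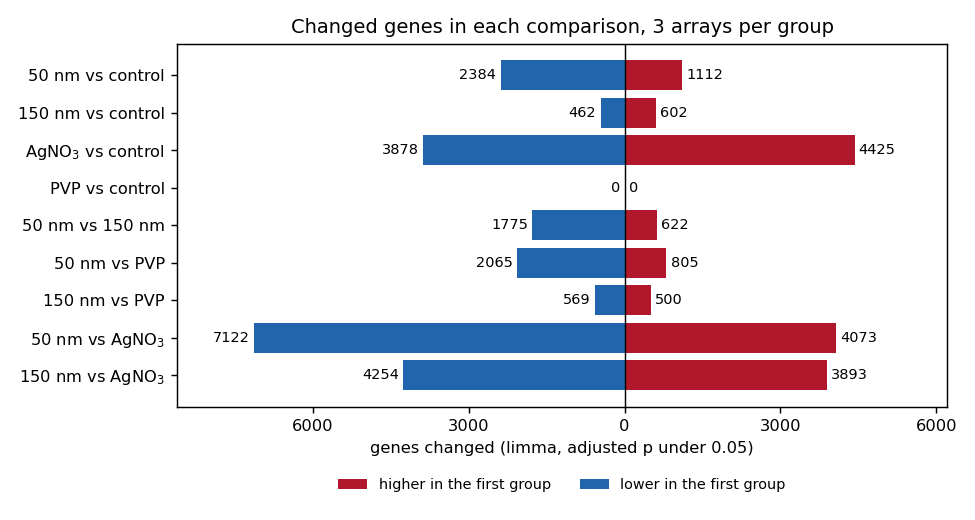
Number of genes with an adjusted p under 0.05 (limma) in each of the 9 comparisons, drawn as bars for genes higher and genes lower in the first-named group, of 23790 tested. The 50 nm particles against control gave 1112 higher and 2384 lower, AgNO3 against control 4425 and 3878, and PVP against control 0.

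With 150 nm particles, compared with control, cry3b (1.84 ± 0.17) and cry5 (1.5 ± 0.13), both members of the clock list, rose. The biliverdin reductase genes blvra (1.51 ± 0.18) and blvrb (0.66 ± 0.10) rose too. Among the other rises were wdr76 (2.73 ± 0.20), grem1a (2.21 ± 0.35), fbp2 (1.59 ± 0.25), a fructose bisphosphatase gene, ino80b (1.58 ± 0.25), ddx27 (1.56 ± 0.22), crtac1a (1.53 ± 0.12) and plppr5b (1.45 ± 0.35). The largest falls were in socs3a (−1.32 ± 0.22), a suppressor of cytokine signalling, the HSP90 partner gene chordc1a (−1.26 ± 0.12), six7 (−1.22 ± 0.11), rhcga (−1.20 ± 0.12), cpo (−1.17 ± 0.21), endou (−1.12 ± 0.27), jdp2b (−1.10 ± 0.20), dhrs13a.2 (−1.09 ± 0.14), slc28a1 (−1.07 ± 0.17) and the retinol dehydrogenase gene rdh8b (−1.07 ± 0.15). With slide as a fixed block grem1a (−0.18) and plppr5b (−0.50) turned lower. Near background, stim1b was at least 4.45-fold lower.

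Proteasome genes were lower as a set at the preset correlation, but not at the estimated one of 0.496 (adjusted p = 0.628), with a median of −0.35 over 50 genes, 14 lower and 1 higher, among them psmb7 (−0.72 ± 0.12), a core subunit gene, psmd4a (−0.74 ± 0.13) and psmd3 (−0.63 ± 0.12); adjusted over the list alone 24 fell and 1 rose. Chaperone genes had a median of −0.19, with serpinh1b (−0.90 ± 0.22) and dnaja1 (−0.96 ± 0.24) lower and hspa9 (0.56 ± 0.12) higher of 31, and adjusted over the list alone 6 lower and 1 higher. The unfolded protein response list had 2 of 30 lower, dnajc3a (−0.80 ± 0.12) and xbp1 (−0.40 ± 0.08), at a median of −0.16. No pancreatic enzyme gene passed, but their median was −0.67 and 6 were lower adjusted over the list alone. Heme genes lay higher, with 5 of 38 rising (slc25a38a at 0.73 ± 0.12, tspo at 0.91 ± 0.16, fech at 0.88 ± 0.20), and adjusted over the list alone 5 higher and 1 lower. The set tests gave adjusted p = 2.33e-13 (proteasome), 3.67e-09 (pancreas), 0.000196 (chaperone), 0.00106 (unfolded protein response) and 0.012 (heme), and 0.628 for the others too with an estimated correlation. With slide as a fixed block the proteasome median was −0.80, and the pancreas call ended (adjusted p = 0.124). That block sets 150 nm against control through 50 nm replicate 3, whose proteasome mean was 0.28. The 150 nm arrays stood at −0.37 to −0.16 and the controls at −0.03 to 0.13.

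Smaller shifts covered 5 more lists, each lower as a set: oxidative phosphorylation (median −0.11, 3 of 88 lower), lens (−0.15, 0 of 60), muscle (−0.08, 1 of 84, klhl40a at −0.92 ± 0.14), enterocyte (−0.11, 1 of 43, the peptide transporter gene slc15a1b at −0.48 ± 0.12) and epidermis (−0.10, 3 of 55, stard14 at −0.79 ± 0.14 and krt15 at −0.44 ± 0.11). With adjustment within the list 2, 0, 1, 5 and 5 of these were lower, and 1 enterocyte gene was higher. Their adjusted p was 0.000285, 0.00188, 0.0107, 0.012 and 0.0186, and 0.628 to 0.67 with an estimated correlation. All 5 were lost under quantile normalization (adjusted p from 0.0944 to 0.834), where the muscle median turned to 0.02, and the fixed slide block turned the muscle and oxidative phosphorylation tests to higher and ended the lens and enterocyte calls (adjusted p = 0.285 and 0.106). Normexp ended the muscle, enterocyte and epidermis calls (adjusted p = 0.209, 0.209 and 0.234). Among lists that did not pass, 13 of 37 clock genes rose and 3 fell (median −0.01, mean 0.17, adjusted p = 0.137), and 8 of 32 inflammation genes fell and 2 rose (adjusted p = 0.107); adjusted over the list alone these were 14 and 10, and 9 and 4. The inflammation list did pass with slide as a fixed block (median −0.42, adjusted p = 0.000103) and as a random one (median −0.14, adjusted p = 0.00541). The fixed block sets 150 nm against control through 50 nm replicate 3, which stood highest for inflammation (0.91). The 150 nm arrays stood at −0.24 to −0.16 and the controls at −0.20 to 0.10. With the fixed block the apoptosis list passed lower, and the cell cycle, hepatocyte, neural and photoreceptor lists higher (medians −0.24, 0.33, 0.28, 0.25 and 0.24), and with the random one the cell cycle list. Median, mean and test also differed in sign for metal binding (−0.02, 0.02, lower) and hepatocyte genes (−0.02, 0.03, higher), and the ionocyte test pointed lower at a median of 0.03. In fry 0 lists passed by its directional p. Of the stress genes followed throughout, hmox1a rose (0.65 ± 0.14), as did gstp1.2 (0.58 ± 0.16, adjusted p = 0.0488), and gpx1a fell (−0.38 ± 0.07), while no change was called in mt2 (−0.01 ± 0.22), hsp70l (−0.47 ± 0.45), atf3 (−0.08 ± 0.17), cat (0.37 ± 0.13), il1b (−0.73 ± 0.79), sod1 (0.13 ± 0.09), sod2 (0.08 ± 0.08), gstp1.1 (−0.16 ± 0.31) or cyp1a (0.05 ± 0.18).

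In total 1064 genes changed, 602 higher and 462 lower, with 120 at least 2-fold. Groups did not overlap at 8150 genes (34.4%, chance 10%). With only these 2 groups the count was 2830. Leaving out one array gave 242, 530 and 312 without control replicates 1, 2 and 3, and 384, 438 and 503 without 150 nm replicates 1, 2 and 3. A random slide block left 65 genes, all shared, and a fixed block 520, of which 96 were shared in direction and 2 were opposite. Of the 20 named genes the random block kept 9, among them wdr76, cry3b, cry5, blvra and six7.

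AgNO3 at 20 µg/L, compared with control, was followed by falls in most genes of the cell cycle, oxidative phosphorylation and pancreatic enzyme lists. The clock gene per2 (−2.97 ± 0.18) fell most among named genes well above background, and other large falls were in the histone gene hist1h2a11 (−2.84 ± 0.33), taf5l (−2.83 ± 0.16), thnsl2 (−2.25 ± 0.29), hist1h2a3 (−2.23 ± 0.18), tsnax (−2.21 ± 0.18), the apolipoprotein gene apoa4a (−2.15 ± 0.30), cpa1 (−2.00 ± 0.30) and cdca7a (−1.90 ± 0.21). Rises were led by isca1 (2.48 ± 0.56), which encodes an iron-sulfur cluster assembly protein, pkp2 (1.76 ± 0.25), cab39 (1.71 ± 0.18), the proteasome gene psmb12 (1.70 ± 0.34), glceb (1.69 ± 0.16), the defensin gene defbl2 (1.69 ± 0.25), ddx27 (1.67 ± 0.22), pltp (1.66 ± 0.28), desi1a (1.66 ± 0.37) and ccnf (1.62 ± 0.22). Near background, the intelectin gene itln2 was at least 28.1-fold higher, mfap4.4 at least 15.8-fold lower and the hatching enzyme gene he1.2 at least 15.7-fold lower.

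Of 57 cell cycle genes 40 fell and 1 rose (median −0.69), with the replication genes gins2 (−1.58 ± 0.18), mcm5 (−1.49 ± 0.21) and rrm2l (−1.49 ± 0.19) among them. Of 88 oxidative phosphorylation genes 63 fell and 2 rose (median −0.42), including ndufb9 (−0.81 ± 0.09) and cox7c (−0.67 ± 0.07). Pancreatic enzyme genes had the lowest median, −1.27, and 21 of 26 fell, such as the trypsin gene prss1 (−1.49 ± 0.19) and ctrb.2 (−1.73 ± 0.25). Of 84 muscle genes 47 fell and 4 rose, including pvalb2 (−1.26 ± 0.12), a calcium-binding protein gene, and ckma (−0.85 ± 0.10). Antioxidant genes fell in 20 of 39 cases and rose in 2, with sod1 at −0.96 ± 0.09, prdx4 at −1.10 ± 0.11 and gsta.1 at −1.25 ± 0.15. Adjusted over the list alone these falls numbered 46, 69, 21, 48 and 21. The sets gave adjusted p = 3.4e-13 (cell cycle), 9.65e-19 (oxidative phosphorylation), 5.47e-10 (pancreas), 1.41e-09 (muscle, lost under quantile normalization at 0.395) and 2.24e-08 (antioxidant). With an estimated correlation they were adjusted p = 0.31, 0.109, 0.364, 0.31 and 0.0901.

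Epidermis genes fell in 21 of 55 cases, the keratin genes krt91 (−1.17 ± 0.10) and krt4 (−0.96 ± 0.10) among them, and rose in 1 (adjusted p = 6.18e-07, and 0.0832 with an estimated correlation). Photoreceptor genes fell in 28 of 60 cases and rose in 4 (arr3b at −0.98 ± 0.10, pde6ha at −1.02 ± 0.12; adjusted p = 1.01e-06, and 0.276 with an estimated correlation). Lens genes fell in 23 of 60 cases and rose in 3, crygs1 at least 8.23-fold, but under quantile normalization the list's median was 0.02 (adjusted p = 0.994, against 0.000105 in the planned scaling and 0.527 with an estimated correlation). Xenobiotic metabolism genes fell in 30 of 68 cases (cyp2k19 at −1.28 ± 0.17), enterocyte genes in 20 of 43 with 9 higher (the fatty acid binding protein gene fabp1b.1 at −1.71 ± 0.17, the bile acid transporter gene slc10a2 at 1.44 ± 0.16), and hepatocyte genes in 16 of 54 (apoa2 at −0.84 ± 0.09, rbp4 at −1.24 ± 0.15). Heme genes fell in 13 of 38 (hbae3 at −1.13 ± 0.20), unfolded protein response genes in 8 of 30 (calr at −1.08 ± 0.17) and sterol biosynthesis genes in 6 of 26 (insig1 at −1.29 ± 0.22). With each list adjusted alone, falls in these lists numbered 21 (epidermis), 30 (photoreceptor), 24 (lens), 31 (xenobiotic), 20 (enterocyte), 16 (hepatocyte), 13 (heme), 8 (unfolded protein response) and 6 (sterol). The last 6 sets gave adjusted p = 0.000134, 0.00148, 0.00744, 0.0314, 0.024 and 0.0421, and with an estimated correlation adjusted p = 0.109, 0.364, 0.44, 0.441, 0.506 and 0.506. Normexp ended the last 4 of them and quantile normalization the hepatocyte, heme and unfolded protein response calls.

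The other 9 lists did not pass camera. For these the counts of genes higher and lower were 6 and 15 of 37 clock genes (adjusted p = 0.0659), 13 and 17 of 68 neural genes, 8 and 4 of 50 proteasome genes, 7 and 9 of 35 apoptosis genes, 4 and 7 of 26 metal binding genes, 3 and 8 of 31 chaperone genes, 6 and 7 of 51 ionocyte genes, 4 and 5 of 32 inflammation genes and 5 and 9 of 43 leukocyte genes. With each list adjusted alone these changed by at most 1, to 16 lower for clock, 14 higher for neural, 10 lower for apoptosis and 5 and 6 for ionocyte genes. The proteasome list passed under quantile normalization (median 0.19, adjusted p = 0.0326). In fry 13 lists passed. Inflammation and leukocyte medians were −0.10 and −0.05 against means of 0.04 and 0.03. Of the other stress genes cat (−0.83 ± 0.13), gstp1.1 (−1.28 ± 0.31), sod2 (−0.42 ± 0.08) and gpx1a (−0.49 ± 0.07) fell, as did gstp1.2 (−0.82 ± 0.16). No change was called in mt2 (−0.31 ± 0.22), hmox1a (−0.33 ± 0.14), hsp70l (0.70 ± 0.45), atf3 (0.22 ± 0.17), cyp1a (0.24 ± 0.18) or il1b (−0.71 ± 0.79).

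AgNO3 changed 8303 genes, 4425 higher and 3878 lower, with 1383 at least 2-fold, and 46.7% were lower, or 57% after normexp. Of the changed genes with a symbol 1741 were higher and 2593 lower, so probes without a symbol leaned higher. All 14 lists called lay lower, and lists of genes with a symbol can do so for that reason. Groups did not overlap at 13771 genes (58.2%, chance 10%). Each left-out array kept the count between 6425 and 6668. A random slide block gave 3189, all shared, and kept all 20 of the named genes with the largest changes, but AgNO3 had no array on another slide, so no fixed block could be fitted.

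**Figure D2:**
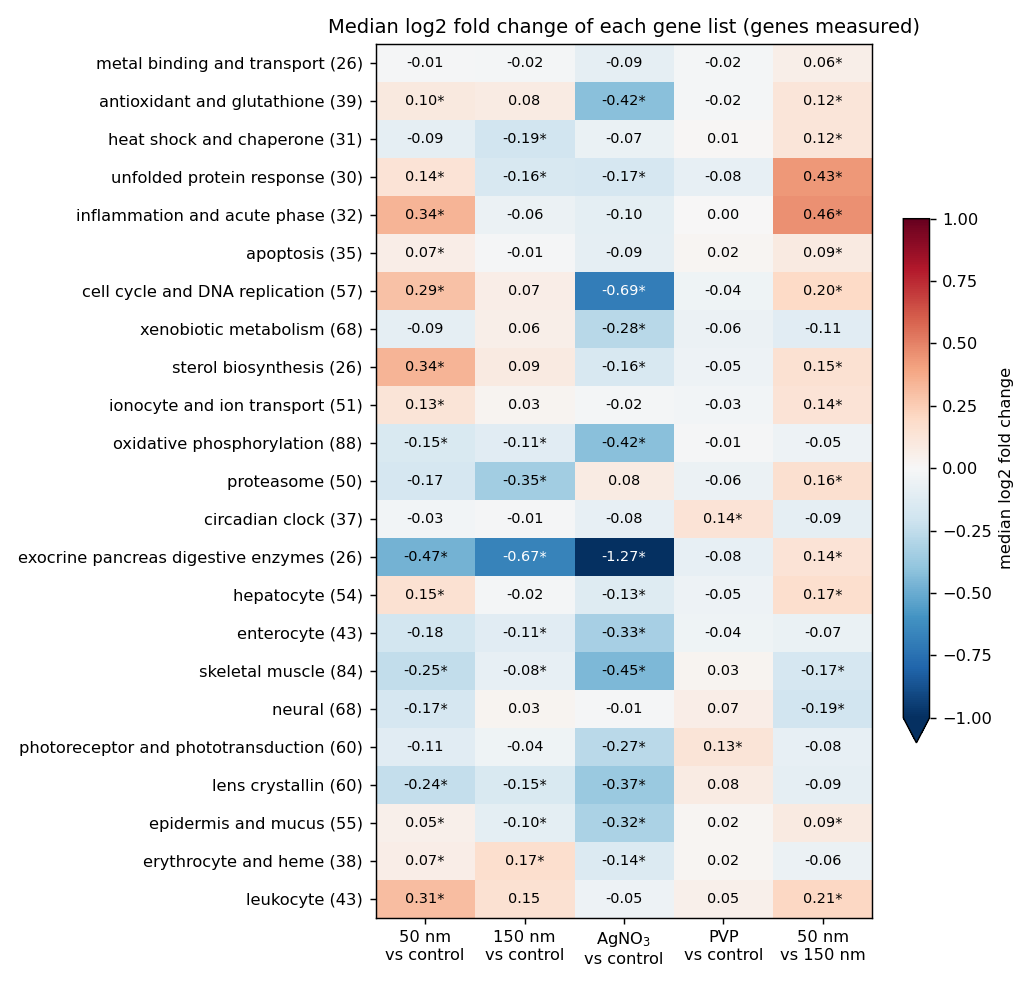
Median log2 fold change of the genes of 23 lists (vertical) in the first 5 comparisons (horizontal), as colour, with an asterisk where camera at the preset correlation gave an adjusted p under 0.05. The pancreatic enzyme list had medians of −0.47, −0.67 and −1.27 with 50 nm particles, 150 nm particles and AgNO3 against control, and the cell cycle list 0.29, 0.07 and −0.69; the lens median with AgNO3 turns to 0.02 under quantile normalization.

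PVP, the coating without silver, was compared with control to ask what the coating does alone. The genes with the smallest p were stim1b (lower, and near background on all 3 PVP arrays), klf9 (0.50 ± 0.10), slc25a38a (0.62 ± 0.12), gata5 (−0.42 ± 0.09) and klf3 (0.46 ± 0.10), all short of the threshold (adjusted p = 0.348 to 0.371). Clock genes had a median of 0.14 over 37 genes and photoreceptor genes 0.13 over 60, with no single gene past the test (nfil3-6 at 0.56 ± 0.16, cry1a at 0.21 ± 0.08, guca1d at 0.48 ± 0.12). As sets both lay higher (adjusted p = 0.000332 and 0.00437, but 0.586 and 0.91 with an estimated correlation). With slide as a fixed block, where PVP is replicate 1 alone, 12 lists passed in either direction, with a random one 6, without PVP replicate 2 there were 8, and without any other array of the 2 groups 2 to 4. Adjusted over the list alone 2 muscle and 2 heme genes were higher. The other lists had medians from −0.08 to 0.08 and did not pass, the proteasome list by the least (adjusted p = 0.0501), and fry passed 0 lists. Metal binding and inflammation had medians of −0.02 and 0.00, means of 0.03 and 0.05 and tests pointing lower. The stress genes ranged from −0.23 ± 0.45 (hsp70l) to 0.38 ± 0.17 (atf3), with mt2 at −0.19 ± 0.22, hmox1a at −0.06 ± 0.14, sod1 at −0.12 ± 0.09, sod2 at −0.13 ± 0.08, cat at 0.08 ± 0.13, gpx1a at −0.08 ± 0.07, gstp1.1 at 0.24 ± 0.31, cyp1a at 0.00 and il1b at −0.19 ± 0.79, none past the test.

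By limma 0 genes changed between PVP and control (smallest adjusted p = 0.348), with 2380 at an unadjusted p under 0.05; no other tool was run per gene. Slide as a random or a fixed block also gave 0 (839 and 581 unadjusted). Without PVP replicate 1 the count was 950, 752 higher and 198 lower. Within slide 1, PVP replicate 1 against the 3 controls gave 4 genes. Groups did not overlap at 4007 genes (17%, chance 10%).

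Compared directly at the same mass concentration, 50 nm particles gave higher expression than 150 nm particles of inflammation and unfolded protein response genes as sets at the preset correlation, but not with an estimated one (adjusted p = 0.143 and 0.155). Replicate 3 stood highest of the 50 nm arrays (0.91 against 0.17 and 0.10 for inflammation, 0.46 against 0.22 and −0.01 for unfolded protein response). Rises included rgs2 (2.82 ± 0.27), odc1 (2.39 ± 0.35), the immediate early gene egr3 (2.36 ± 0.13), rgs13a (2.29 ± 0.18), f2rl1.2 (1.96 ± 0.17), a protease-activated receptor gene, the transcription factor gene cebpb (1.96 ± 0.14), ptgs2b (1.93 ± 0.20), and the jacalin family genes jac6 (2.05 ± 0.54), jac8 (1.97 ± 0.55) and jac9 (2.03 ± 0.59). The jacalin calls held without 50 nm replicate 2, and ended when any other array of either size was left out. Lower with 50 nm were bhlha9 (−1.34 ± 0.18), the fetuin gene ahsg2 (−1.34 ± 0.30), mocos (−1.21 ± 0.15), foxq1b (−1.18 ± 0.14), cry3b (−1.10 ± 0.17), prcc (−1.0 ± 0.16), tspan34a (−1.0 ± 0.21), the growth factor gene fgf20b (−0.93 ± 0.23), med22 (−0.89 ± 0.23) and rc3h1b (−0.88 ± 0.15). The AP-1 gene fosl1a, near background at 150 nm, was at least 13.3-fold higher. Of the stress genes atf3 (1.31 ± 0.17) and hsp70l (1.5 ± 0.45, adjusted p = 0.0491) were higher, the latter not called without 50 nm replicate 1 or any 150 nm array, nor with normexp, quantile normalization or no dim filter, and no difference was called in mt2 (0.54 ± 0.22), hmox1a (0.02 ± 0.14), il1b (2.09 ± 0.79), sod1 (−0.12 ± 0.09), sod2 (−0.15 ± 0.08), cat (0.04 ± 0.13), gpx1a (−0.02 ± 0.07), gstp1.1 (0.04 ± 0.31) or cyp1a (−0.21 ± 0.18).

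Of 32 inflammation genes 10 were higher with 50 nm and none lower (ptgs2a at 1.70 ± 0.17, fosab at 1.26 ± 0.18, junbb at 1.11 ± 0.14), and of 30 unfolded protein response genes 11 were higher (hyou1 at 0.99 ± 0.19, pdia4 at 0.86 ± 0.17, xbp1 at 0.44 ± 0.08). Adjusted over the list alone the counts were 12 higher and 1 lower, and 15 higher and 1 lower. Chaperone genes were higher in 5 of 31 cases (hsp90aa1.1 at 0.81 ± 0.21, hspb1 at 0.81 ± 0.24), epidermis genes in 8 of 55 (cldnb at 1.37 ± 0.13, stard14 at 1.37 ± 0.14), and apoptosis genes in 6 of 35 with 2 lower (btg2 at 1.73 ± 0.21, gadd45bb at 0.87 ± 0.11). Ionocyte genes had 6 of 51 higher and 1 lower (rhcga at 0.54 ± 0.12), hepatocyte genes 6 of 54 higher and 1 lower (serpina7 at 1.86 ± 0.33), and leukocyte genes 5 of 43 higher (cxcr4b at 0.51 ± 0.13). With each list adjusted alone these 6 lists had 8, 10, 7, 6, 9 and 6 higher. The sets gave adjusted p = 4.66e-10 for inflammation and unfolded protein response, 1.03e-05 for chaperone and epidermis, 0.000457 for apoptosis, 4.49e-06 for ionocyte and leukocyte and 4.87e-05 for hepatocyte. With an estimated correlation all were at adjusted p = 0.143 to 0.179. Of these, the fixed slide block, where 50 nm is replicate 3 alone, ended the hepatocyte call (adjusted p = 0.25).

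Further lists higher with 50 nm were proteasome (3 of 50, psmd8 at 0.53 ± 0.12, adjusted p = 1.44e-08), cell cycle (0 of 57, median 0.20, 2.4e-07), antioxidant (3 of 39, txnipa at 0.52 ± 0.09, 0.000252), sterol biosynthesis (2 of 26, fdps at 0.35 ± 0.08, 0.000799), pancreas (0 of 26, median 0.14, 0.0304) and metal binding (1 of 26, slc30a7 at 0.28 ± 0.08, median 0.06, mean −0.03, 0.0434). The proteasome means were −0.03, −0.32 and 0.28 on the 50 nm arrays and −0.37 to −0.16 on the 150 nm arrays, so 50 nm replicate 2 lay within the 150 nm range and replicate 3 highest. With adjustment within the list 1, 0, 2, 4, 0 and 3 were higher, and 3 metal binding genes were lower. With an estimated correlation these had adjusted p = 0.336, 0.379, 0.166, 0.321, 0.837 and 0.165. The pancreas list turned lower with slide as a fixed block (median −0.38) and without 50 nm replicate 2 (median −0.13). The fixed block also ended the antioxidant, cell cycle and metal binding calls (adjusted p = 0.0594, 0.0925 and 0.0996), and quantile normalization the last (adjusted p = 0.0881). Neural genes were lower in 10 of 68 cases (the acetylcholinesterase gene ache at −0.44 ± 0.10, neurod1 at −0.38 ± 0.09; adjusted p = 0.00111) and muscle genes in 7 of 84 (ryr1b at −0.54 ± 0.11, myoz1a at −0.55 ± 0.10; adjusted p = 0.0294), against 0.379 and 0.778 with an estimated correlation; adjusted over the list alone 13 and 7 were lower. The other 7 lists did not pass, with medians from −0.11 to −0.05, and of these the xenobiotic, oxidative phosphorylation, enterocyte, lens and heme tests pointed higher against a negative median. With the fixed block, and so from 50 nm replicate 3 alone, 3 of them passed lower, oxidative phosphorylation, photoreceptor and lens (medians −0.16, −0.27 and −0.34). In fry 6 lists passed, 5 that passed camera and the clock list.

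Between particle sizes 2397 genes changed, 622 higher and 1775 lower with 50 nm (74.1% lower), with 377 at least 2-fold. Of the changed genes with a symbol 403 were higher and 750 lower, so probes without a symbol leaned lower by more. Groups did not overlap at 6536 genes (27.7%, chance 10%). The count was 1489 after normexp and 50 with only these 2 groups. Without 50 nm replicates 1 and 2 in turn it was 836 and 4475, and without 150 nm replicates 1, 2 and 3 it was 834, 849 and 882. A random slide block gave 1765, 1428 of them shared, and kept 18 of the 20 largest named changes; a fixed block gave 3946, 1166 of them shared. Within slide 3, 50 nm replicate 3 against the 150 nm arrays gave 3170.

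**Figure D3:**
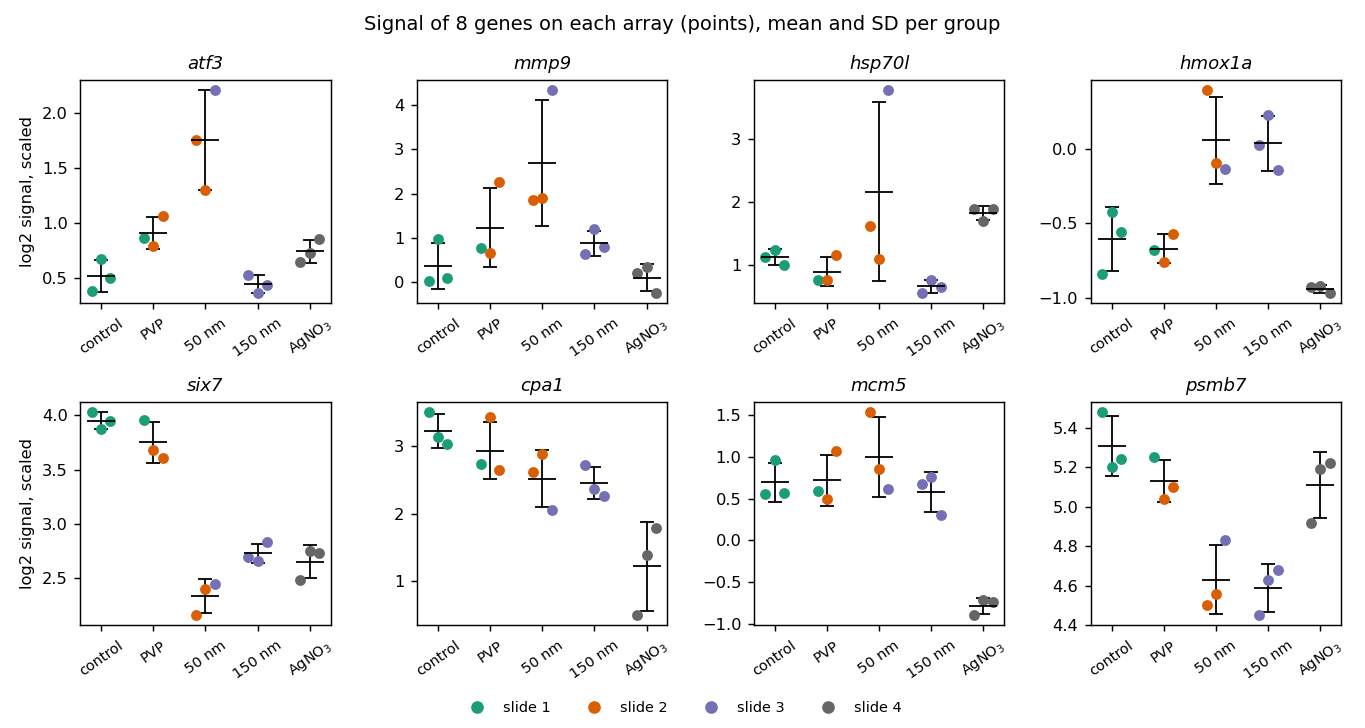
Log2 intensity relative to each array's 75th percentile (vertical) of 8 genes in the 5 groups (horizontal), one point per array coloured by slide, with the group mean ± SD. For atf3 the 50 nm arrays lie at 1.3 to 2.21 and the controls at 0.39 to 0.68, while hsp70l and mmp9 are highest in 50 nm replicate 3 (3.78 and 4.34).

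Against the same controls, 75 genes rose and 104 fell in all 3 silver groups. The largest mean changes with a symbol were in fbp2 (1.58, 1.59 and 1.09 with 50 nm, 150 nm and AgNO3), six7 (−1.62, −1.22 and −1.30), ino80b (1.2, 1.58 and 1.28), ddx27 (0.80, 1.56 and 1.67), prxl2b (1.15, 1.23 and 0.92), fkbp11 (−0.62, −0.74 and −1.83), slc12a10.3 (1.37, 0.81 and 0.91) and btr12 (1.18, 1.15 and 0.68). Their SE ran from 0.11 (six7) to 0.25 (fbp2 and ino80b). With PVP, which held no silver, the same genes stood at 1.1 (fbp2), −0.20 (six7), 0.65 (ino80b), 0.64 (ddx27), 0.53 (prxl2b), −0.11 (fkbp11), 0.32 (slc12a10.3) and 0.89 (btr12) against control, none past the test. On PVP replicates 2 and 3, which lay on slide 2, ino80b (2.65 and 2.73), ddx27 (1.51 and 1.5), prxl2b (−1.08 and −1.09) and btr12 (1.07 and 1.1) lay above the controls, while PVP replicate 1, on the controls' slide, did not (1.41, 0.34, −1.99 and −0.18). For fbp2 all 3 PVP arrays did (1.44 to 2.39 against 0.51 to 1.33). The prolactin gene prl2, near background with 50 nm, was at least 2.23-fold lower there, and cdc37l1 at least 6.16-fold lower. On the 3 PVP arrays cdc37l1 was low as well (−5.81 to −5.51, against −4.92 to −2.83 in controls), and prl2 stood at −4.66 to −4.29 (controls −4.26 to −3.99). The other probes of ddx27 give another direction with 50 nm when averaged in (−0.09), and with slide as a fixed block ino80b (0.00) and btr12 (−0.06) lost theirs with 50 nm. In place of 179 genes there were 21, 106 and 29 without control replicates 1, 2 and 3. A random slide block left 7.

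The sizes shared 495 genes called in the same direction, 222 higher and 273 lower (28.1 and 46.3 by chance), and 27 called in opposite directions. Shared controls alone can raise such counts. With separate controls, 308 genes were shared when 50 nm was set against PVP and 150 nm against control (20.4 higher and 40.1 lower by chance), and 37 were opposite. When the sets were exchanged 306 were shared and 56 opposite. Fold changes of the sizes correlated across genes at 0.49 (simulated unchanged groups sharing controls gave 0.5), and at 0.27 and 0.10 with separate controls. Their covariance was 0.0676 (simulated 0.0239). The overlap was 90 and 118 without control replicates 1 and 3, 32 with a random and 8 with a fixed slide block. With AgNO3, 50 nm shared 252 rises and 599 falls (206.8 and 388.6 by chance) with 520 opposite, and 150 nm shared 245 and 176 (112 and 75.3) with 165 opposite. These 851 and 421 shared genes became 169 and 70, 768 and 182, and 213 and 115 without control replicates 1, 2 and 3. With slide as a random block 58 and 10 were shared, with only the 2 groups 138 and 1261, with array weights 1770 and 2073, and with a replicate block 662 and 250. Fold changes correlated with those of AgNO3 at 0.14 (50 nm) and 0.26 (150 nm), where simulated unchanged groups gave 0.5. Their covariances with AgNO3 were 0.0317 and 0.0456, above the 0.0238 and 0.0239 of the simulated groups. The low correlations alone therefore do not show less sharing than shared controls give.

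**Figure D4:**
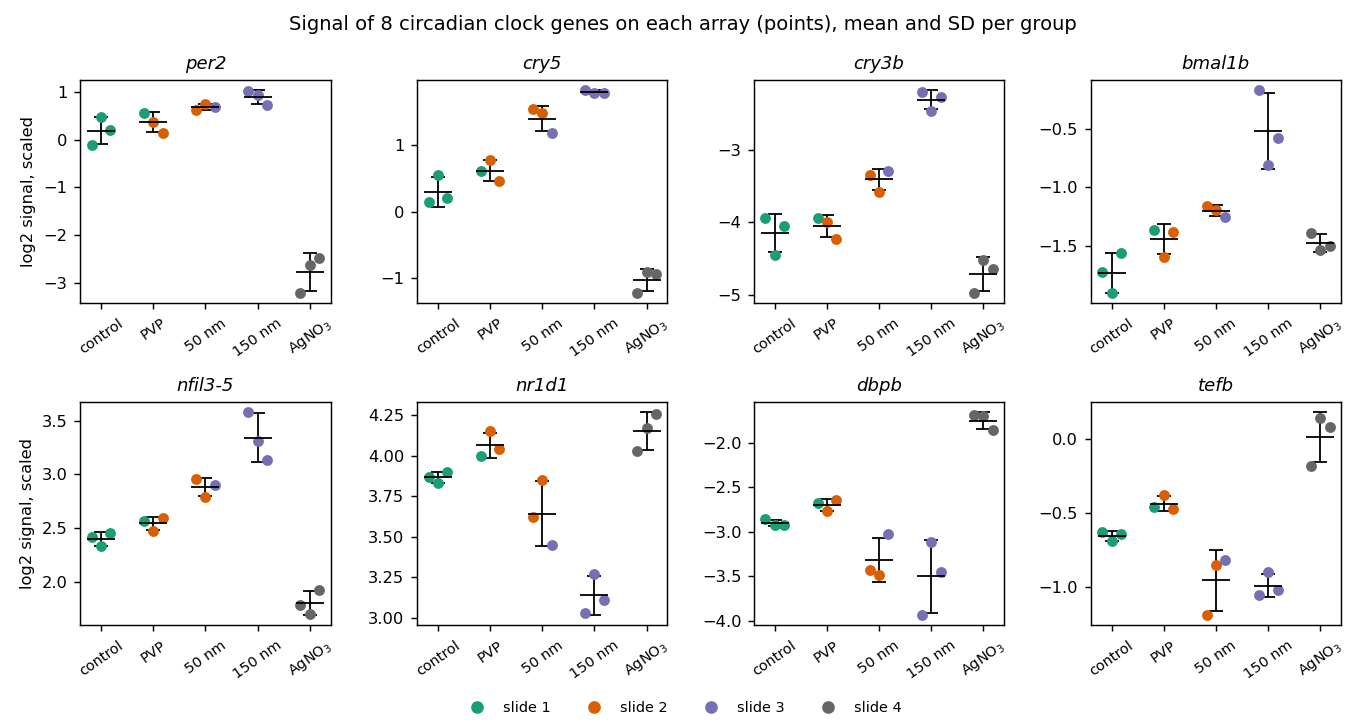
Log2 intensity relative to each array's 75th percentile (vertical) of 8 clock genes in the 5 groups (horizontal), one point per array coloured by slide, with the group mean ± SD. The AgNO3 arrays, all on slide 4, lie at −3.22 to −2.48 for per2 and the other arrays at −0.10 to 1.02.

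Some of the 37 clock genes are given here because members of the list passed in opposite directions. With 150 nm particles cry5, cry3b and per2 (0.71 ± 0.18) rose, as did the activator genes bmal1b (1.21 ± 0.14) and bmal1a (0.45 ± 0.09) and the repressor gene nfil3-5 (0.94 ± 0.10), while nr1d1 (−0.73 ± 0.10) and per1b (−0.51 ± 0.09) fell. With 50 nm particles cry5 (1.11 ± 0.13), cry3b (0.74 ± 0.17), bmal1b (0.53 ± 0.14) and nfil3-5 (0.49 ± 0.10) rose and per1b fell (−0.54 ± 0.09), with per2 at 0.50 ± 0.18 (adjusted p = 0.0747). With AgNO3 cry5 (−1.32 ± 0.13), bmal1a (−0.73 ± 0.09) and nfil3-5 (−0.60 ± 0.10) fell with per2, while dbpb (1.15 ± 0.18), tefb (0.67 ± 0.11) and nr1d1 (0.29 ± 0.10) rose.

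Particles were also compared with their coating. With 50 nm against PVP, ptgs2b (1.67 ± 0.20), ptgs2a (1.25 ± 0.17), kcnj1a.3 (2.46 ± 0.45) and the bile acid synthesis gene cyp7a1 (2.03 ± 0.39) rose. Higher as sets were cell cycle (5 of 57 higher, pcna at 0.72 ± 0.20, cdk1 at 0.88 ± 0.22), leukocyte (8 of 43, mpeg1.2 at 1.14 ± 0.31), inflammation (6 of 32), sterol biosynthesis (9 of 26, sqlea at 1.23 ± 0.30), hepatocyte (15 of 54 and 2 lower), ionocyte (12 of 51 and 3 lower), unfolded protein response (3 of 30, atf3 at 0.85 ± 0.17) and antioxidant genes (7 of 39 and 2 lower, hmox1a at 0.73 ± 0.14, gstp1.2 at 0.77 ± 0.16, keap1b at −0.73 ± 0.13), with adjusted p from 5.23e-14 (cell cycle) to 2.84e-05 (antioxidant), and adjusted p = 0.21 to 0.257 with an estimated correlation. Within each list alone these had 14, 16, 8, 13, 20, 15, 3 and 7 higher. The apoptosis, xenobiotic, heme and epidermis lists lay higher by less (adjusted p = 0.0254, 0.0284, 0.0284 and 0.0341, and 0.282, 0.282, 0.371 and 0.282 with an estimated correlation), the epidermis list at a median of −0.02 and a mean of 0.04. Lower were muscle (17 of 84 and 1 higher, myoz1a at −0.71 ± 0.10, adjusted p = 8.6e-07), neural (9 of 68, snap25a at −0.31 ± 0.07, 0.000183), lens (5 of 60, 0.00242), pancreas (0 of 26, median −0.42, 0.0175) and photoreceptor genes (10 of 60, guca1c at −0.93 ± 0.12, 0.0176), and oxidative phosphorylation (9 of 88 and 1 higher, 0.019), whose test turned higher under quantile normalization (median −0.03, adjusted p = 0.835). With an estimated correlation these had adjusted p = 0.282, 0.282, 0.633, 0.653, 0.447 and 0.623, adjusted over the list alone 37, 10, 1, 0, 15 and 5 were lower, and quantile normalization ended the xenobiotic, pancreas, muscle, photoreceptor and lens calls. Normexp ended the oxidative phosphorylation and photoreceptor calls (adjusted p = 0.0504 and 0.0569). Slide as a fixed block ended the apoptosis, oxidative phosphorylation, pancreas, neural, photoreceptor and epidermis calls (adjusted p = 0.169, 0.26, 0.134, 0.0769, 0.248 and 0.134) and set the proteasome list lower (median −0.20, adjusted p = 0.0109). Of the remaining lists the metal binding, chaperone and proteasome tests pointed higher at medians of 0.00, −0.04 and −0.03. In fry 10 lists passed, 9 of them also in camera.

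In the same comparison 2870 genes changed, 805 higher and 2065 lower, with 346 at least 2-fold, and 72% were lower, or 60.7% after quantile normalization. The median over all genes was −0.104. Groups did not overlap at 6393 genes (27.1%, chance 10%). The count was 6 with only the 6 arrays of these groups, 777 and 1478 without PVP replicates 2 and 3, and 844 and 5313 without 50 nm replicates 1 and 2. Random and fixed slide blocks gave 3216 and 2552, with 2730 and 1578 shared. Within slide 2 (2 arrays against 2) 0 genes passed limma, with 4233 at an unadjusted p under 0.05.

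With 150 nm against PVP, rdh8b (−1.17 ± 0.15), the guanylate cyclase activator gene guca1c (−0.90 ± 0.12) and psmd11b (−0.68 ± 0.14) fell. Lists lower as sets at the preset correlation, though not with an estimated one (adjusted p = 0.617), were proteasome (7 of 50, psmb6 at −0.50 ± 0.10, adjusted p = 6.47e-08), pancreas (0 of 26, median −0.59, 2.55e-06), lens (1 of 60, crygm2d14 at −0.61 ± 0.12, 0.000112), chaperone (1 of 31, dnaja1 at −0.88 ± 0.24, 0.000122), epidermis (6 of 55, the plakophilin gene pkp3a at −0.81 ± 0.13, 0.0189), photoreceptor (5 of 60 and 1 higher, 0.0189) and unfolded protein response genes (2 of 30, xbp1 at −0.43 ± 0.08, 0.0257). Muscle (2 of 84 lower and 1, myod1 at 0.48 ± 0.11, higher) and oxidative phosphorylation (1 of 88) were lower too (adjusted p = 0.00259 and 0.00872). Neither passed with an estimated correlation, and their tests turned higher under quantile normalization (medians −0.01 and 0.00). Within each list alone the falls in these 9 lists numbered 19, 0, 1, 9, 10, 10, 2, 2 and 0. Cell cycle genes lay higher (0 of 57, median 0.18, adjusted p = 0.0106, and 0.708 with an estimated correlation). Quantile normalization ended the unfolded protein response, photoreceptor, lens and epidermis calls (adjusted p = 0.0984, 0.26, 0.162 and 0.802), and normexp the unfolded protein response, photoreceptor and epidermis calls (adjusted p = 0.0519, 0.195 and 0.101). The fixed slide block turned the pancreas, photoreceptor, lens, muscle and oxidative phosphorylation lists higher or to a test pointing higher, with medians from −0.01 to 0.10. With that block the inflammation (median −0.54) and apoptosis lists passed lower, and the xenobiotic, hepatocyte, neural and heme lists higher. That fit sets 150 nm against PVP through 50 nm replicate 3, which stood highest for inflammation (0.91). A random block ended the oxidative phosphorylation, muscle, photoreceptor and lens calls. The clock list had a median of −0.17 and a mean of 0.03, the neural list 0.01 and −0.02.

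The 150 nm group differed from PVP at 1069 genes, 500 higher and 569 lower, with 102 at least 2-fold, and groups did not overlap at 7107 (30%, chance 10%). With only these 2 groups 691 changed. The count was 2049, 253 and 356 without PVP replicates 1, 2 and 3, and 328, 378 and 472 without 150 nm replicates 1, 2 and 3. The random slide block gave 212 and the fixed block 1906, with 207 and 349 shared. In fry 0 lists passed.

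Compared with AgNO3, larvae given 50 nm particles had higher per2 (3.47 ± 0.18), cry5 (2.42 ± 0.13), ptgs2b (2.4 ± 0.20) and fabp1b.1 (2.28 ± 0.17), and lower slc10a2 (−2.23 ± 0.16) and rgs9b (−1.09 ± 0.09). Of the 23 lists 21 lay higher at the preset correlation, of which 2 passed with an estimated one. Both normexp and quantile normalization ended the metal binding (adjusted p = 0.163 and 0.195), chaperone (0.0872 and 0.195), clock (0.116 and 0.177) and enterocyte calls (0.116 and 0.195), and normexp the lens call (0.059). Antioxidant genes (26 of 39 higher and 1 lower, txnipa at 1.19 ± 0.09, gsto2 at 1.48 ± 0.13, gstp1.2 at 1.65 ± 0.16, adjusted p = 1.46e-11) and epidermis genes (28 of 55 and 2 lower, krt91 at 1.05 ± 0.10, 6.2e-09) also passed with an estimated correlation (adjusted p = 0.0281 for both). The cell cycle list had the highest median (1.16, 45 of 57 higher, rrm2l at 2.12 ± 0.19, adjusted p = 2.13e-19, and 0.147 with an estimated correlation). Within each list alone 26, 28 and 46 of these were higher. For the muscle and lens lists (29 of 84 and 19 of 60 higher) the test turned lower under quantile normalization (medians −0.08 and −0.12). In total 11195 genes changed, 4073 higher and 7122 lower, with 2336 at least 2-fold, and groups did not overlap at 12410 (52.6%, chance 10%). Of the changed genes with a symbol 2669 were higher and 2976 lower, so probes without a symbol leaned lower. Lists of genes with a symbol can lie higher for that reason. The median over all genes was −0.137, and in fry 15 lists passed. With the random slide block the metal binding and enterocyte calls ended (adjusted p = 0.0635 and 0.0719). That block gave 6857 genes, 6856 of them shared.

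Larvae given 150 nm particles had higher per2 (3.68 ± 0.18), cry5 (2.82 ± 0.13), cry3b (2.41 ± 0.17), sod1 (1.09 ± 0.09), cat (1.2 ± 0.13) and krt4 (1.1 ± 0.10) than those given AgNO3, and lower proteasome genes such as psmd11b (−1.02 ± 0.14) and psma5 (−1.01 ± 0.17). Cell cycle (45 of 57 higher and 1 lower, gins2 at 1.57 ± 0.18, adjusted p = 1.07e-13) and antioxidant genes (21 of 39 and 1 lower, gstp1.2 at 1.4 ± 0.16, 1.74e-07) were among 13 lists that lay higher, and the proteasome list (26 of 50 lower and 2 higher, median −0.46, 1.17e-06) lay lower. With an estimated correlation these had adjusted p = 0.294, 0.116 and 0.452, and none of the 14 passed; adjusted over the list alone 46 cell cycle and 21 antioxidant genes were higher and 27 proteasome genes lower. The lens list was higher (20 of 60, adjusted p = 0.0307) but its test turned lower under quantile normalization (median −0.11). That setting also ended the clock, hepatocyte, muscle and epidermis calls (adjusted p = 0.154, 0.178, 0.387 and 0.192), and normexp the clock and lens calls (adjusted p = 0.171 and 0.121). The unfolded protein response test pointed higher at a median of −0.06, the apoptosis median was 0.00, and in fry 12 lists passed. In total 8147 genes changed, 3893 higher and 4254 lower, with 1491 at least 2-fold, and groups did not overlap at 12996 (54.8%, chance 10%). Of the changed genes with a symbol 2470 were higher and 1896 lower, so here too probes without a symbol leaned lower. The random slide block gave 3938, all shared. Over the 5 groups together the limma F test called 12702 genes (53.4%), and 6648 with the random slide block.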

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

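The tests of the PVP arrays, of the clock genes and of slide for the 50 nm result, and the random slide block in comparisons without AgNO3, were chosen only after the result was seen.

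Some genes moved in opposite directions with the 2 particle sizes. Relative to control, 27 genes moved one way with 50 nm and the other way with 150 nm particles, and all 27 also differed in the direct comparison of the sizes, which is what drew attention to them. Of these 24 were higher with 50 nm and lower with 150 nm. They include egr3 (1.76 with 50 nm, −0.61 with 150 nm), cebpb (1.41 and −0.56), ptgs2b (1.11 and −0.81), ptgs2a (1.08 and −0.63), btg2 (0.82 and −0.91), cldnb (0.90 and −0.48) and sgk1 (0.80 and −0.38), while bhlha9 (−0.61 and 0.73) went the other way, with SE from 0.10 (sgk1) to 0.21 (btg2). Quantile normalization gave 25 such genes and a random slide block 0. Within slide 3, 50 nm replicate 3 lay beyond all 3 arrays of 150 nm at all 27 genes, in the direction of 50 nm against control (median 1.29, 0.64 to 2.61). Within slide 2 both 50 nm arrays lay beyond both PVP arrays at all 27 (median 0.66, 0.20 to 1.98). Differences inside a slide are not differences between slides, but the genes were chosen on these same arrays and 50 nm had 1 array on slide 3. No slide held both 150 nm or 50 nm and control arrays, so an effect of slide on the moves against control was not excluded. Genes listed here were chosen after their values were seen.

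PVP replicates 2 and 3 stood apart from control at 950 genes once replicate 1 was left out, 79.2% of them higher. Their median change was 0.76, while replicate 1, which shared the slide of the controls, had 0.02 in the same direction (59.5% of genes). With replicate 1 kept, 0 genes passed at equal weights and 1099 with array weights, where its weight was 0.512. The 950 genes were chosen without replicate 1, and 1 array is too few to decide. The slide 2 arrays of the 50 nm group differed from their slide 3 array in the same direction at 71.8% of these genes, again with 1 array on slide 3. Slide 2 and exposure therefore cannot be told apart here. The 150 nm and AgNO3 arrays, on other slides, moved 76.6% and 82.7% of these genes the same way against control. The genes were chosen against these same controls, which by itself raises such shares. An effect of the control slide is therefore neither shown nor excluded by them.

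The clock genes split by function with AgNO3. Genes of the Bmal arm of the clock (6) had a median of −0.28 and those of the Per and Dbp arm (13) 0.29, a gap of −0.56; 3 of the 6 fell, and of the 13, 6 rose and 2 fell. Random divisions of the same genes gave a gap as large with exact permutation p = 0.0373 (adjusted p = 0.042). The division was made after clock genes were seen to move apart, and it treats genes that are regulated together as independent, so this p does not decide. With 50 nm and 150 nm particles the gap was 0.65 and 0.73 (exact permutation, adjusted p = 0.00814 and 0.0089). A shift of clock phase may account for such gaps, as a hypothesis that only samples from several times of day could decide. Slide 4, which held the AgNO3 arrays alone, sampling time and silver cannot be told apart as its source, because 0 lines of the labels name a time of day or a light cycle.

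The count for 50 nm against control went from 3496 genes to 11 with slide as a fixed block and 414 with a random one. For the 3496 genes the median change in the called direction was 0.54 (median SE 0.13), and 0.43 (median SE 0.21) with the fixed block, with 97.4% in the same direction, so the calls ended with a wider SE as well as a smaller change. To look within slide 2 without choosing genes on it, 5889 genes were called from 50 nm replicate 3 and the controls with all slide 2 arrays left out, 2225 of them among the 3496 in the same direction. Within slide 2 the 50 nm arrays differed from PVP at these genes by a median of 0.19 in that direction (74.8% of genes), and by 0.08 to 0.32 in the 4 pairs of arrays. The other 2 divisions of these 4 arrays gave 0.07 and 0.11. The real division gave more than the other 2, but its lowest pair (0.08) lay below 1 of them (0.11). These genes were called from 1 array of 50 nm, whose array weight (0.235) was the lowest, and 4 arrays can be divided only 3 ways. Over all genes the median was −0.087 against control and −0.104 against PVP, so a shift common to both could contribute. Whether slide was the whole cause for these genes therefore stays open. By limma 0 genes were called within slide 2 alone (4233 at an unadjusted p under 0.05). The size of the slide's part stays open, since no control array lies on slides 2 or 3.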

How the results depend on the processing

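The random slide block in comparisons without AgNO3 was chosen only after the result was seen. The deposited value table, the mean of probes and the stricter filter moved none of 23 counts by over 1.5 times. Causes of the counts and directions below were not tested, except that the 2-fold rule is stricter by construction. Arrays left out and fits of only 2 groups use fewer samples, yet some counts rose. The main fit shares 1 spread among groups, so SEs for 50 nm (array weights 0.901, 0.419 and 0.235) may be too small. For 50 nm against control (3496 genes) the count was 5699 with no dim filter, 296 with only 2 groups, 11 with a fixed and 414 with a random slide block, 5344 with array weights and 466 at 2-fold, and 770 to 5135 with an array left out. For 150 nm against control (1064) it was 2830 with 2 groups, 520 and 65 with fixed and random slide blocks, 700 with a replicate block, 4400 with weights, 120 at 2-fold, and 242 to 530. AgNO3 against control (8303) gave 3189 with the random block and 1383 at 2-fold (6425 to 6668), and PVP against control (0) 1099 with weights (0 to 950). The sizes (2397) gave 1489 with normexp, 50 with 2 groups, 3946 with the fixed block, 377 at 2-fold, and 834 to 4475. 50 nm against PVP (2870) gave 6 with 2 groups, 346 at 2-fold, and 777 to 5313. 150 nm against PVP (1069) gave 691 with 2 groups, 1906 and 212 with fixed and random blocks, 3092 with weights, 102 at 2-fold, and 253 to 2049. Against AgNO3, 50 nm (11195) gave 6857 with the random block and 2336 at 2-fold (9360 to 11357), and 150 nm (8147) 3938 and 1491 (6277 to 6636). Any group (12702) gave 6648 with the random block (10256 to 13916). The overlap of sizes (495) was 173 with 2 groups, 8 and 32 with fixed and random blocks, 1720 with weights, 308 and 306 with separate controls, and 90 to 333. All 3 silver groups (179) gave 99 with 2 groups, 7 with the random block, 114 with a replicate block, 786 with weights, and 21 to 106. Numbers of lists called by camera fell with an estimated correlation to 2 for 50 nm against AgNO3 and to 0 elsewhere. By fry they were 5 of 16 for 50 nm and 0 of 10 for 150 nm against control, 0 of 2 for PVP, 6 between sizes (5 of the 16 and the clock list), and 10 (9 of the 18 and the clock list) and 0 of 10 for 50 nm and 150 nm against PVP. Quantile normalization gave 5 for 150 nm against control and against PVP, 4 for PVP against control and 9 (of 14) for 150 nm against AgNO3. PVP against control had 4 with no dim filter, 12 with the fixed and 6 with the random block, and 2 to 8 with an array left out (4 without PVP 3, control 1 or control 3, 8 without PVP 2); 50 nm against control had 10 to 17 (10 without 50 nm replicate 3).

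Lists called in at least 1 of the 2 fits whose test reversed with slide as a fixed block had these medians: 150 nm against control, oxidative phosphorylation −0.02, muscle −0.04, photoreceptor 0.24; PVP against control, muscle −0.06, lens −0.17; between sizes, oxidative phosphorylation −0.16, pancreas −0.38, lens −0.34; 50 nm against PVP, proteasome −0.20; 150 nm against PVP, oxidative phosphorylation 0.07, pancreas 0.02, muscle −0.01, neural 0.16, photoreceptor 0.10, lens 0.05. By the same rule quantile normalization reversed oxidative phosphorylation in 50 nm and 150 nm against PVP (−0.03 and 0.00), muscle in 150 nm against PVP (−0.01), muscle and lens in 50 nm against AgNO3 (−0.08 and −0.12) and lens in 150 nm against AgNO3 (−0.11). With an array left out, pancreas between sizes ran from −0.13 (without 50 nm replicate 2) to 0.36, photoreceptor between sizes from −0.15 to −0.02 (its test reversed without 50 nm replicate 3), and proteasome for 50 nm against PVP from −0.18 (without 50 nm replicate 3) to 0.08. Named genes that reversed were, with the mean of probes, actc1a (0.02) and ddx27 (−0.09) for 50 nm and sdf2l1 (0.01) for AgNO3 against control; with the fixed block, btr12 (−0.06), ddx27 (−0.42) and ino80b (0.00) for 50 nm and btr12 (−0.06), grem1a (−0.18) and plppr5b (−0.50) for 150 nm against control, and grk7b (0.05) for 150 nm against PVP; and with no dim filter rilpl1 between sizes (1.48). Of the other results, 1126 of 1242 list results with an array left out stayed on their side, 76 were weaker and 37 stronger; for named genes these were 3363, 527 and 46 of 3936. Quantile normalization left 622 of 656 named genes on their side, with 30 weaker and 4 stronger, normexp 595, 39 and 22, the random block 521, 132 and 3, and the fixed block 241, 156 and 13 of 417. Signal over background limits genes near background: without the dim filter 31042 genes were tested and with the stricter one 18688, and the median of all genes with AgNO3 was 0.126 without the filter. In fits of only PVP replicate 1 or 50 nm replicate 3 within a slide, limma pools the spread, so the lone sample is assumed to vary like the other groups.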

Other observations

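No test was added for the splits below, while the divisions of clock genes for other comparisons were chosen only after the result was seen.

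Single arrays carried part of the stress response with 50 nm particles. In replicate 3 hsp70l stood at 3.78 (log2 intensity relative to the array's 75th percentile) against 0.55 to 1.89 on the other 14 arrays, il1b at −0.51 against −5.67 to −3.59, and mmp9 at 4.34 against at most 2.27. The mean of the inflammation list was 0.91 on that array and −0.24 to 0.17 elsewhere. By contrast atf3 was raised on all 3 arrays of the group (1.3 to 2.21), and hmox1a lay above every control on all 6 particle arrays (−0.14 to 0.40 against −0.84 to −0.42). These genes come from the fixed lists, but this reading of single arrays was chosen after their values were seen.

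Of 18 histone genes, a group that no list covered and that was chosen after its values were seen, 13 fell and 1 rose with AgNO3 against control (median −0.52), hist1h2a11 and hist1h2a3 the most. With 50 nm particles 1 fell and with 150 nm particles 0 changed; set directly against AgNO3, 11 were higher and 2 lower with 50 nm and 13 higher with 150 nm. No test of the group was run. The gene grem1a was high on every array of slides 2 and 3 (0.06 to 0.89), the PVP arrays there included (0.12 and 0.50), and low on slides 1 and 4 (−1.83 to −1.19).

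In the comparison of the sizes the gap between the clock arms was −0.30 (exact permutation p = 0.0239, adjusted p = 0.0307), and in PVP against control −0.08 (exact permutation p = 0.269). Of the genes called for 50 nm against control 68.2% were lower, 61.9% with quantile normalization, 66.1% among the brighter genes and 63.5% to 69.5% with an array left out. That share was 46.2% with no dim filter, 44.6% (of 296 genes) with only the 2 groups and 27.3% (of 11) with slide as a fixed block.

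The 6 arrays of a comparison can be split 10 ways, which is too few for a share under 0.05. With the other groups kept in the limma fit, the real split and the highest of the others gave 3496 and 51 genes for 50 nm against control, 1064 and 0 for 150 nm against control, 8303 and 0 for AgNO3 against control, 2397 and 4 between sizes, 2870 and 301 for 50 nm against PVP, 1069 and 6 for 150 nm against PVP, 11195 and 8 for 50 nm against AgNO3 and 8147 and 0 for 150 nm against AgNO3. In each of these only 1 of the 10 splits, the real one, reached the real count. For PVP against control, at a real count of 0, all 10 splits did and the highest other was 1. For the 5 groups together 1 of 100 drawn splits, the real one with 12702 genes, reached the real count and the highest other was 6604, so chance can be excluded there for arrays drawn without regard to slide. The groups follow the slides, so this leaves slide open.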
